A study of Mus musculus with 4 samples.

How the data were processed

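RNA sequencing of primary hepatocytes from C57BL/6 mice gave 4 libraries, each assigned to its group by the genotype in the labels: β-gal overexpression, Purβ overexpression, scramble and Purβ knockdown. Per the labels' protocols, total RNA was extracted with a commercial phenol reagent and libraries followed standard Illumina procedures. The labels name more than 1 short hairpin virus for the knockdown arm and do not say which of them was used for the library labelled Purβ knockdown. The infection lasted 30 h in that arm and overnight in the overexpression arm. Whether the libraries kept strand, whether they were selected for polyadenylated RNA, and the read length are not given in the sources used here.

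The deposited values are FPKM (fragments per kilobase of gene, scaled to library size), 1 table per library with 55918 genes, their length and their coordinates. Per the submitters' processing notes, TopHat2 and HTSeq 0.6.1 were used with the genome build GRCm38. Of the gene identifiers, 55450 are in the reference annotation at hand for this build, and all of these have identical coordinates there. For every library, FPKM times gene length was a whole multiple of a common step within 0.001 reads for 100% of the values above 0, so that whole reads per gene were recovered. These reads gave totals of 15764869 (β-gal), 16455447 (Purβ overexpression), 23730298 (scramble) and 16433291 (library labelled Purβ knockdown), in 20735, 22481, 23376 and 23908 genes. The library size that the authors used as the FPKM denominator was not this total: its ratio to the recovered total was 0.825, 0.897, 1.10 and 1.26 in the same order. A further scale factor per library, whose source is not given in the sources used here, is therefore part of the deposited FPKM. It moves every gene of a library by the same factor and none of the rankings within a library.

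Each comparison used log2 of FPKM plus a pseudocount of 1, treated minus control, over the 12097 genes with a mean of at least 1 FPKM in the 4 libraries. This scale understates the fold of weakly expressed genes. Overexpression was set against β-gal, the library labelled Purβ knockdown against scramble, and scramble against β-gal. Without replicates no test was run, and genes were counted by a fixed size of 2-fold. The ratio of FPKM carries a 95% exact conditional binomial (Clopper-Pearson) interval from the recovered reads. A ratio against 0 reads is given as a bound from a floor of 3 reads in that library. Depth sets the precision: Purb with 1813 reads had a ratio interval of 621 to 681, while G6pc with 4 and 32 reads had one of 0.0406 to 0.445.

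Before the data were examined, 30 gene lists with 486 distinct genes were fixed. They covered hepatocyte metabolism, stress and inflammation, the cell cycle and the markers of 5 other classes of liver cells, and 15 genes stood in more than 1 list. The comparisons, the pseudocount, the filter, the size rules and 8 alternative settings were also chosen before the data were examined. For each list with at least 5 measured members, the median log2 fold was placed among the medians of 10000 random lists of the same size, matched on mean FPKM in 20 bins. A list is said to stand apart below the 2.5 or above the 97.5 percentile, as a description of these libraries and not as a test. The lists for stellate cells and fibroblasts, cholangiocytes, and lymphocytes and granulocytes had 3, 4 and 1 measured members and gave no value.

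The genes named followed a rule fixed beforehand, which took 130 genes: Purb and its paralogs Pura and Purg, 10 genes of hepatic glucose output and its control, and the 10 protein-coding genes with the highest and the 10 with the lowest fold past 2-fold in each arm with at least 5 FPKM in the higher library. It also took up to 4 members with the largest folds from each list that stood apart, and up to 10 protein-coding genes past 1.5-fold in opposite directions in the arms, ranked by the smaller fold. Some genes that the rule took are not reported here. Genes outside the rule are said to have been picked after their values were seen or are named because they make up a count of 5 or fewer. Of the 130 genes, 39 overlap an annotated feature on the other strand, and reads of such pairs cannot be told apart unless the counting used strand.

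The settings tried were a pseudocount of 0.1, no filter, a filter at 5 FPKM, protein-coding genes only, each library scaled to the same median ratio, each library scaled to an equal sum without the 100 most abundant genes, reads scaled to the recovered total of each library, and the other control library as the reference. Scaling to the total without the reads of Purb and Smoc2 was added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

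The procedure was tested on simulated data, in which reads were drawn for the 12097 genes from the real levels and depths with 200 genes changed. The simulated libraries differed by counting error only. The numbers below therefore say nothing about other differences between libraries, such as those behind the 2468 genes past 2-fold between the real controls. For overexpression against β-gal, the 95% interval held the true ratio for 95.6% of genes. In that simulation 49 of 50 genes raised 4-fold, 44 of 50 raised 3-fold, 42 of 50 lowered 4-fold and 40 of 50 lowered 3-fold passed the size rule, as did 77 of 11897 unchanged genes. For the library labelled Purβ knockdown against scramble, the corresponding numbers were 47, 45, 45 and 42 of 50, and 37 of 11897. Of 200 lists of 16 genes drawn at random from the real folds of that comparison, 4.5% stood apart, and 99.5% did once shifted up by 1 log2 unit. The first share follows from drawing at random. Both therefore check the calculation only and say nothing about lists of genes related by function.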

Results

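RNA was measured in primary mouse hepatocytes, the main metabolic cells of the liver, isolated from C57BL/6 animals and infected in culture with adenoviruses. Purβ, the product of Purb, is a single-stranded nucleic acid binding protein of the Pur family. The 4 libraries formed 4 groups. A β-galactosidase (β-gal) control and a Purβ overexpression library came from cells infected overnight. A scramble control and a Purβ knockdown library came from cells infected for 30 h with short hairpin viruses. Each group held 1 library, so no difference below has a replicate check and no p-value is given: every statement compares libraries, not conditions. The read totals recovered from the deposited values were 15764869 for β-gal, 16455447 for Purβ overexpression, 23730298 for scramble and 16433291 for the library labelled Purβ knockdown. Log2 folds are of FPKM plus 1, ratios are of FPKM with their 95% counting interval, and both intervals and detection floors cover counting error only.

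Purb itself served as the check of the labels. The gene lies on chromosome 11 of GRCm38 from 6467599 to 6475917 on the minus strand (ENSMUSG00000094483). Its FPKM was 16.8 in β-gal, 10894 in Purβ overexpression, 10.9 in scramble and 14.2 in the library labelled Purβ knockdown, from 1813, 1337145, 2364 and 2447 reads. Purb was thus higher by 9.26 on the log2 scale in the overexpression library, a ratio of 650.0 (621 to 681), and it took 8.13% of that library's reads. Gene-level values do not separate the introduced sequence from the endogenous transcript. Purb also overlaps 1 annotated feature on the other strand, and reads of such a pair cannot be told apart unless the counting used strand. In the library labelled Purβ knockdown, Purb was not lower than in scramble but higher, with a ratio of 1.31 (1.24 to 1.38) and a log2 fold of 0.36. This goes against the label, so that library is named by its label throughout and each direction drawn from it rests on the label alone. Set against the β-gal library instead, Purb there had a log2 fold of -0.22. The paralog Pura stood at 7.71, 8.06, 10.5 and 10.2 FPKM in the same order of libraries, and Purg at 2.02, 2.51, 2.68 and 4.02 FPKM.

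**Figure D1:**
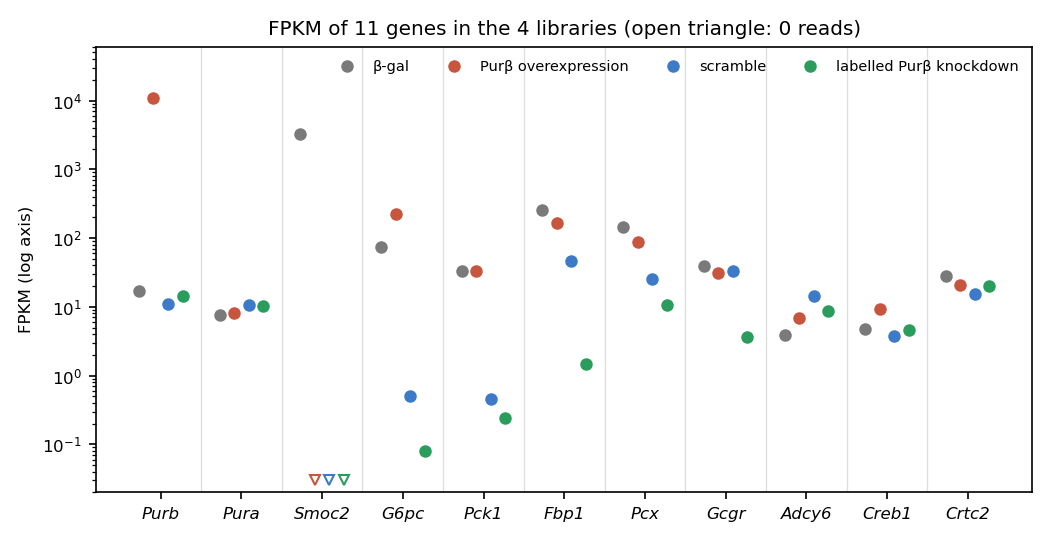
FPKM on a log axis of Purb, Pura, Smoc2 and 8 genes of glucose output in the 4 libraries, 1 point per library, with open triangles at the bottom for 0 reads. Purb stands at 10894 FPKM in the overexpression library and between 10.9 and 16.8 elsewhere, Smoc2 has reads in β-gal only, and G6pc and Pck1 lie below 1 FPKM in scramble and in the library labelled Purβ knockdown.

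The first comparison set Purβ overexpression against β-gal and was meant to address what a gain of Purβ does to the hepatocyte transcriptome. With 1 library each, it cannot separate such an effect from a trait of the β-gal library. Inflammatory and acute phase transcripts were lower in the overexpression library, while G6pc, p53 targets and cell cycle genes were higher. G6pc, the catalytic subunit of glucose-6-phosphatase and the last enzyme of gluconeogenesis, went from 74.6 to 227 FPKM, a ratio of 3.04 (2.90 to 3.18). The other genes of glucose output did not share that difference. Pck1, the cytosolic phosphoenolpyruvate carboxykinase, stood at 33.4 and 33.0 FPKM with a ratio of 0.988 (0.921 to 1.06). Fbp1 and Pcx, which encode fructose bisphosphatase and pyruvate carboxylase, had log2 folds of -0.59 and -0.74, and the glucose-6-phosphate transporter Slc37a4 had 0.11. Among the signalling genes upstream, Adcy6, an adenylyl cyclase, had a log2 fold of 0.69 with a ratio of 1.77 (1.55 to 2.02), and Creb1 had 0.85 with a ratio of 1.97 (1.82 to 2.14). The glucagon receptor Gcgr had -0.35 and the CREB coactivator Crtc2 had -0.41. Against scramble in place of β-gal, Fbp1 (1.81), Pcx (1.72), Adcy6 (-0.94) and Crtc2 (0.40) had the other direction, and Pck1 was at 4.54. Ppargc1a stayed below 1 FPKM in all 4 libraries, at 0.455 in β-gal and 0.637 in overexpression, with a ratio of 1.40 (0.924 to 2.15) that includes 1. As a group, the 14 measured gluconeogenesis genes had a median log2 fold of -0.37, at the 34.2 percentile of 10000 random lists, with G6pc at least 2-fold higher and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, at least 2-fold lower (-1.39).

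Of the 17 NF-kB targets and chemokines, 14 were at least 2-fold lower in the overexpression library and none was 2-fold higher, with a median of -2.10 that was below each of the 10000 random lists. The monocyte chemokine Ccl2 went from 721 to 5.24 FPKM, 138 times lower (112 to 172). The adhesion molecule Vcam1 was 161 times lower (108 to 251), and Ccl7 and Ccl5 had log2 folds of -3.45 and -3.31. Several of these genes were highest in β-gal among all 4 libraries: Vcam1 had 29.4 FPKM there, 0.183 in overexpression, 2.25 in scramble and 0.355 in the library labelled Purβ knockdown, and Ccl5 had 57.9, 4.94, 2.67 and 12.6. Against scramble the NF-kB median was -0.98 and Ccl2 stayed lower (-6.52), while Ccl5 was higher (0.69). Of the 20 acute phase genes, 13 were 2-fold lower and none was higher, with a median of -1.45 that was also below all random lists. Saa3 was 44.3 times lower (41.1 to 47.7), and Il1rn, Orm2 and Lcn2 had log2 folds of -2.78, -2.72 and -2.18. Of 21 interferon response genes, 7 were 2-fold lower and none was higher, with a median of -0.81 below all random lists. Gbp2 led them at -2.32, followed by Irf7 at -1.40, Bst2 at -1.39 and Isg15 at -1.38.

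Among p53 targets, 7 of 16 were at least 2-fold higher and 1, Fas, was 2-fold lower, with a median of 0.98 above all random lists. Pmaip1, which encodes the pro-apoptotic protein Noxa, had a ratio of 8.16 (5.85 to 11.7), Phlda3 had 3.46 (3.08 to 3.88), and Mdm2 and Eda2r had log2 folds of 1.30 and 1.19. Among cell cycle genes, 7 of 24 were 2-fold higher and none lower, with a median of 0.54 above all random lists. These included the cyclin Ccne2 (2.04), the ribonucleotide reductase subunit Rrm2 (1.84), the thymidylate synthase Tyms (1.71) and Ccnb2 (1.54). Lists with small positive medians also stood above the central 95% of random lists. The CREB-responsive genes had a median of 0.24 (98.0 percentile), with G6pc, Dusp1 (1.17), Id1 (1.11) and Nr4a2 (1.08) 2-fold higher among 14. This list did not stand apart with a pseudocount of 0.1 or among protein-coding genes only, and against scramble the fold of Id1 was -2.28. The immediate early genes had 0.20 (99.5 percentile), with Jun (1.47) and Dusp1 2-fold higher among 12, Ier3 (-1.10) 2-fold lower and Ier2 (1.00) just short of 2-fold. Lipogenesis genes had a median of 0.14 (99.0 percentile) but a mean of -0.08. The members with the largest folds were lower: Dgat2 (-1.64), Scd1 (-0.87), Me1 (-0.60) and Dgat1 (-0.55). The unfolded protein and integrated stress response list had a median of 0.01 (99.6 percentile) and a mean of -0.25. Its endoplasmic reticulum chaperones Sdf2l1 (-1.78), Pdia4 (-1.42) and Pdia6 (-1.15) were 2-fold lower and Sesn2 (1.10) was 2-fold higher. The 24 ribosomal protein genes had a median of -0.68 at the 2.61 percentile, just inside the central 95%, and none was past 2-fold.

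Over 12097 genes with a mean of at least 1 FPKM, 666 were at least 2-fold higher and 738 at least 2-fold lower in the overexpression library. After Purb, the 9 protein-coding genes with the highest folds were the anaphase-promoting complex inhibitor gene Fbxo5 (3.19, from 1.88 to 25.2 FPKM), the growth arrest gene Gas1 (3.14), Cdk5r1 (2.95), Zfp948 (2.84), the cytokine gene Il17f (2.68), the splicing factor gene Tra2b (2.54), Arl9 (2.41), the chromatin remodeller gene Ino80 (2.30) and Gm12248 (2.27). The lowest fold among these protein-coding genes belonged to Smoc2, which encodes a secreted calcium-binding matrix protein and lies on chromosome 17 from 14279506 to 14404790. It had 290834 reads and 3218 FPKM in β-gal and 0 reads in the other 3 libraries, so that it was at least 110000-fold lower in overexpression against a floor of 3 reads. Then came Ccl2, Saa3, Vcam1, Cilp2 (-4.52), the colony-stimulating factor genes Csf2 and Csf3 (-4.47), the interleukin gene Il23a (-4.36), the NF-kB inhibitor gene Nfkbie (-4.00) and Sprr1b (-4.00). Csf2 had 227 reads in β-gal and 0 in overexpression, at least 85.9-fold lower. Each of these lowest genes was highest in β-gal among the 4 libraries, although scramble came near it for Ccl2 (574 FPKM) and Saa3 (602). Csf3 stood at 30.7 FPKM in β-gal, 0.432 in overexpression, 1.57 in scramble and 1.88 in the library labelled Purβ knockdown. Cilp2 stood at 25.9, 0.173, 0.0533 and 0.482. For such genes β-gal was the library apart from the others. The marker lists of other liver cell types that had a value did not stand apart: the 9 Kupffer cell and macrophage markers had a median of -0.07 and the 5 endothelial markers -0.11. Of 27 lists with a value, 9 stood apart, fewer than the 18 between the control libraries. The 1.35 expected by chance holds only for independent lists of unrelated genes, and the genes of these lists are related by function. Of all genes past 2-fold, 47.4% were on the high side, and this share was 60.4% with median scaling, 70.0% with an equal sum, 65.8% scaled to recovered read totals and 74.2% scaled to these totals without Purb and Smoc2. Against the scramble library in place of β-gal, the median was -0.03 for acute phase genes, -0.33 for p53 targets and -0.20 for the cell cycle, so the p53 and cell cycle medians changed sign and the acute phase median lay on the high side of its random lists, and the interferon (-0.45), unfolded protein (0.0038) and immediate early (0.59) lists no longer stood apart. Among named genes past 2-fold, Cilp2, Il23a, Sprr1b, Ccl5, Id1, Pmaip1, Phlda3, Eda2r, Mup14 and Areg had the other direction against scramble, as did the lipogenesis genes Scd1 (2.12), Me1 (1.05) and Dgat1 (0.07) with smaller folds.

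**Figure D2:**
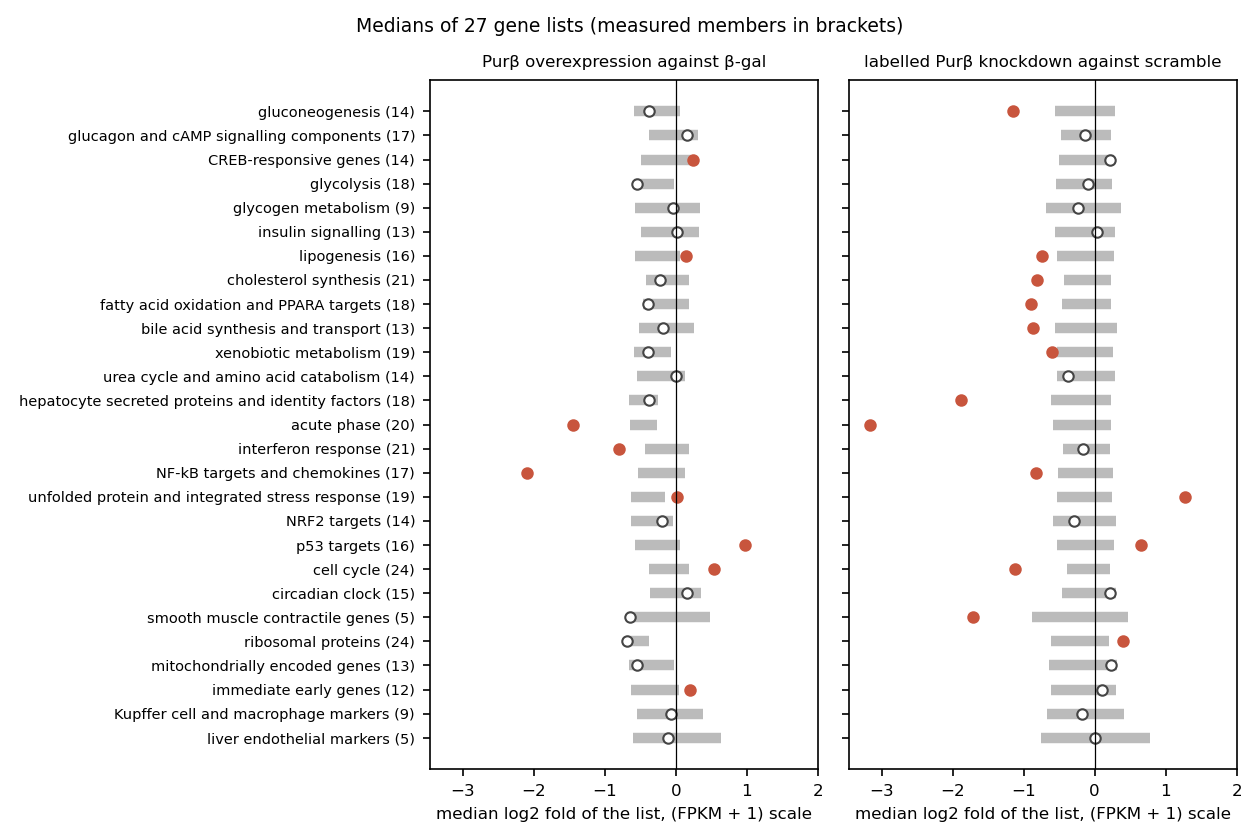
Median log2 fold (x axis, FPKM plus 1 scale) of the 27 gene lists with at least 5 measured members, in each arm. Grey bars give the central 95% of 10000 random lists matched on abundance, and filled points are lists outside it. Acute phase genes lie at -1.45 on the left and -3.17 on the right, and the unfolded protein list lies at 0.01 and 1.28.

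The second comparison set the library labelled Purβ knockdown against scramble and addressed what a loss of Purβ does, although Purb was not lower there. In that library, transcripts of hepatocyte function were lower across many groups, and stress response transcripts were higher. Of 18 hepatocyte secreted proteins and identity factors, 17 were at least 2-fold lower and none was higher, with a median of -1.88 below all 10000 random lists. The fetuin gene Ahsg went from 830 to 15.9 FPKM, 52.1 times lower (48.4 to 56.2). Apob and Apoc3, which encode apolipoproteins, had log2 folds of -3.39 and -3.22, and Hnf4a, a master regulator of hepatocyte identity, had -3.02 and was 10.5 times lower (9.36 to 11.9). Of the 20 acute phase genes, 16 were 2-fold lower, with a median of -3.17 below all random lists. The haptoglobin gene Hp went from 5125 to 95.8 FPKM, 53.5 times lower (51.6 to 55.4), and Fga, Fgb and Steap4 had -4.86, -4.81 and -3.86. The share of reads outside protein-coding genes differed in the same library: protein-coding genes took 97.8% of reads in scramble and 96.1% in the library labelled Purβ knockdown.

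Several metabolic lists lay lower as well in the library labelled Purβ knockdown. Glycolysis (-0.10), glycogen metabolism (-0.24) and the urea cycle and amino acid catabolism (-0.38) did not stand apart. Of 14 gluconeogenesis genes, 8 were 2-fold lower and none was higher, with a median of -1.15 (0.03 percentile). Fbp1 was 32.2 times lower (24.4 to 43.4), Pcx had -1.18, Slc37a4 had -1.23, and Gpt2 and Tat had -2.02 and -1.80. G6pc and Pck1 were near the detection floor in both libraries of this arm, with 32 and 41 reads in scramble and 4 and 17 in the library labelled Purβ knockdown. Their ratios were 0.158 (0.0406 to 0.445) and 0.524 (0.279 to 0.942). The glucagon receptor Gcgr was 9.15 times lower (7.91 to 10.6). Adcy6 had -0.64 with a ratio of 0.618 (0.577 to 0.662), Creb1 had 0.21, Crtc2 had 0.36 and Ppargc1a had -0.03. Against β-gal in place of scramble, Adcy6 (0.99), Creb1 (-0.05) and Crtc2 (-0.46) had the other direction. Of 21 cholesterol synthesis genes, 10 were 2-fold lower and none was higher, with a median of -0.81 below all random lists. Nsdhl (-3.16), Hmgcs1 (-2.39) and Dhcr7 (-2.24) were among those lower. Fatty acid oxidation and PPARA targets had a median of -0.90 (0.03 percentile) with 8 of 18 lower and 2 higher. Angptl4 was at -2.28 and Vnn1 at -2.23, while Pdk4 was at 2.04 but at -0.91 against β-gal. Bile acid genes had -0.87 (0.15 percentile). Abcb4 (-2.82), Nr0b2 (-2.49, from 150 to 2 reads) and the bile acid receptor gene Nr1h4 (-2.30) were lower, and the bile salt export pump gene Abcb11 (2.34) was higher. Lipogenesis had -0.74 (0.42 percentile) with 5 of 16 lower, among them Scd1 (-3.98), Gpam (-2.62), Dgat2 (-1.73) and Elovl6 (-1.22). Xenobiotic metabolism had -0.59 (1.2 percentile) with 7 of 19 lower and 1 higher. Cyp2c70 (-3.62), Gsta1 (-2.66), Gstm1 (-2.48) and the receptor gene Nr1i2 (-2.45) were among those lower.

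Of the 19 unfolded protein and integrated stress response genes, 13 were at least 2-fold higher and none lower in the library labelled Purβ knockdown, with a median of 1.28 above all random lists. Ddit3, which encodes the stress-induced factor CHOP, went from 9.66 to 91.3 FPKM, a ratio of 9.45 (8.54 to 10.5), and Ppp1r15a, Creld2 and Sdf2l1 had log2 folds of 2.74, 2.34 and 2.30. The p53 targets had a median of 0.65 above all random lists, with 4 of 16 higher and 1, Perp (-1.17), lower. Pmaip1 (1.61), Aen (1.10) and Gdf15 (1.06) were among those higher. Ribosomal protein genes had a median of 0.40 (99.98 percentile) with none past 2-fold, and Rpl30 (0.86), Rps2 (0.64), Rpl18 (0.61) and Rps3 (0.59) had the largest folds. Cell cycle genes had a median of -1.12 below all random lists, with 13 of 24 lower and 3 higher. The mitotic genes Cdc20 (-2.81), Mki67 (-2.68), Plk1 (-2.47) and Top2a (-2.40) were lower, while Mcm2, Mcm3 and Mcm4 of the replicative helicase were the 3 at least 2-fold higher. NF-kB targets had -0.82 (0.12 percentile) with 7 of 17 lower and 2 higher, led by Cxcl5 (-3.56), Ccl2 (-3.53) and Cxcl1 (-2.21) against Ccl5 (1.89). The 5 measured smooth muscle contractile genes had a median of -1.71 (0.205 percentile), with Tpm2 (-3.50), Cnn2 (-2.12) and Cald1 (-1.71) past 2-fold and Tpm1 at -0.95.

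Over the same 12097 genes, 732 were at least 2-fold higher and 1493 at least 2-fold lower in the library labelled Purβ knockdown. Among protein-coding genes with at least 5 FPKM in the higher library, the lowest folds were those of Aldh1a1 (-6.22, a ratio of 0.00753), Hp (-5.73), the liver pyruvate kinase gene Pklr (-5.62), Ahsg (-5.62), Wfdc21 (-5.22), Apof (-5.18), the ceruloplasmin gene Cp (-5.08), Ugt2b36 (-4.96), Ubd (-4.87) and Fga. Ubd had 1 read there against 725 in scramble, a ratio of 0.00174 (4.41e-05 to 0.00974). The highest of these protein-coding genes were the ATPase gene Atp13a4 (4.23, from 2.21 to 59.4 FPKM), the heat shock genes Hspa1a (3.63) and Hspa1b (3.02), Gm4969 (3.41), Rgcc (3.26), the purinergic receptor gene P2rx7 (3.14), Ddit3, Derl3 (3.08), Mup14 (2.91) and Gem (2.83). Hspa1a and Hspa1b, the Mup genes, and in part Orm2, Gsta1, Gstm1 and Ugt2b36, share near-identical copies, so their values are uncertain. The marker lists of other liver cell types that had a value did not stand apart, with -0.17 for Kupffer cells and macrophages and 0.01 for endothelium. Of all 22 measured markers of other liver cell types, 6 were at least 2-fold lower and 1 was at least 2-fold higher. Of 27 lists with a value, 14 stood apart. Of genes past 2-fold, 32.9% were on the high side, and 44.1% were after scaling to recovered read totals. Against β-gal in place of scramble the cell cycle and smooth muscle medians were 0.51 and 0.74, so these directions were not kept. Nor, among other named genes past 2-fold, were those of Pdk4, Perp, Ccl5, Mup14, Il23a, Sprr1b and Areg against β-gal. With a filter at 5 FPKM the cell cycle median was 0.53. That filter changes no gene's fold, so the median turned because weakly expressed members were left out.

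The third comparison set the control libraries against each other, since each arm had its own control virus and infection time. Between scramble and β-gal, 2468 genes differed at least 2-fold (1079 higher and 1389 lower in scramble), against 1404 in the overexpression comparison and 2225 in the comparison of the library labelled Purβ knockdown. Of the lists of hepatocyte metabolism and secretion, 8 stood apart on the low side in scramble, while cholesterol synthesis (-0.03, 66.4 percentile) and fatty acid oxidation (-0.23, 23.0 percentile) did not stand apart. Alb went from 16174 to 980 FPKM (-4.04), Fabp1 had a log2 fold of -8.87, Cyp2e1 -8.05, G6pc -5.65, Cps1 of the urea cycle -4.64 and Pck1 -4.56. Apart from G6pc and Pck1, which the rule took, these genes were picked after their values were seen. All of them lie on the low side, while 1 of 18 hepatocyte secreted proteins and identity factors was 2-fold higher and 11 were 2-fold lower. The medians were -3.66 for xenobiotic metabolism, -2.77 for the urea cycle and amino acid catabolism, -2.11 for gluconeogenesis, -1.84 for glycogen metabolism, -1.74 for bile acid genes, -1.70 for lipogenesis, -1.52 for glycolysis and -1.31 for hepatocyte secreted proteins. Lower too were the circadian clock (-1.10), NRF2 targets (-1.08), NF-kB targets (-1.07), acute phase genes (-0.96) and CREB-responsive genes (-0.72), the last of which did not stand apart without a filter. Higher in scramble were Kupffer cell and macrophage markers (2.26), smooth muscle contractile genes (2.08), the cell cycle (1.43), p53 targets (0.73) and ribosomal proteins (0.28). These made 18 lists outside the central 95% of random lists. Of genes past 2-fold, 43.7% were higher in scramble, a share that was 54.1% with median scaling, 60.8% with an equal sum and 72.7% scaled to recovered read totals.

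The last comparison asked whether genes moved in opposite directions with overexpression and with the label of knockdown. Across the 12097 genes, which are not independent replicates, the log2 folds of the arms had a Pearson correlation of 0.22 and a Spearman correlation of 0.22. The arms shared no control library. Past 2-fold in both, 295 genes had the same direction, where independent lists would share 131, and 71 had opposite directions, where independent lists would share 127. An exchange of the scramble and knockdown labels, left open below, would turn every fold of the second arm. Both correlations would then be negative, and same and opposite would swap in the counts at 2-fold and at 1.5-fold. At 1.5-fold, 261 protein-coding genes with at least 5 FPKM in their highest library had opposite directions. Genes with the same direction were not counted at this size. Of these, 133 were higher with overexpression and lower in the library labelled Purβ knockdown, and Adcy6 was among them at rank 202 by its smaller fold, although its direction turned in both arms with the references crossed. The 10 leading genes with at least 5 FPKM in their highest library were Mup14 (-2.80 and 2.91), Gem (-2.38 and 2.83), Il23a (-4.36 and 2.33), Sprr1b (-4.00 and 1.93), Ccl5 (-3.31 and 1.89), the semaphorin receptor gene Plxnd1 (-1.80 and 1.88), Sdf2l1 (-1.78 and 2.30), Rrm2 (1.84 and -1.61), the growth factor gene Areg (-1.70 and 1.52) and Pdia4 (-1.42 and 1.67). With the references crossed, 5 of these 10 genes, Mup14 (1.99 and -1.88), Il23a (2.28 and -4.31), Sprr1b (0.80 and -2.87), Ccl5 (0.69 and -2.11) and Areg (0.48 and -0.66), turned direction in both arms. With the references crossed the correlation was -0.47, where each arm's fold then contains the difference between the controls with opposite sign.

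**Figure D3:**
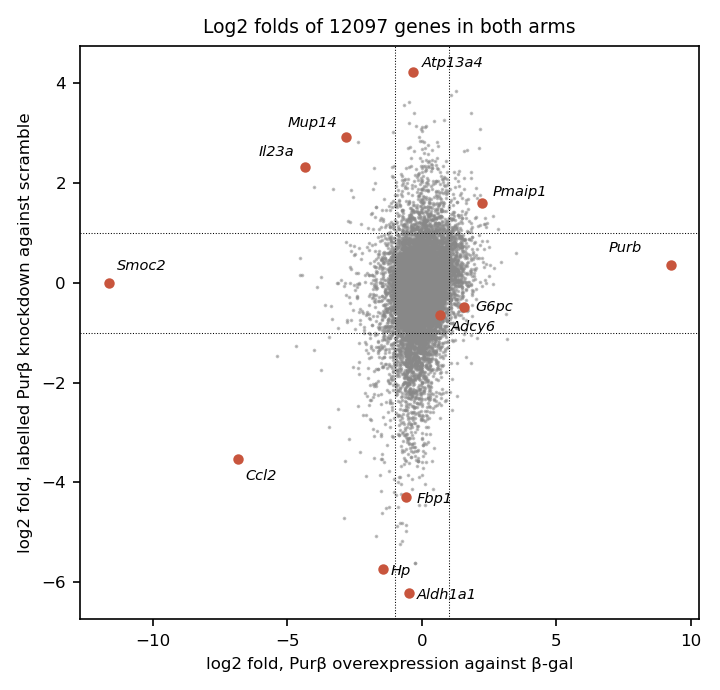
Log2 fold of each of 12097 genes with Purβ overexpression against β-gal (x axis) and in the library labelled Purβ knockdown against scramble (y axis), with dotted lines at 2-fold. Each grey point is a gene and named genes are marked; Purb lies at 9.26 and 0.36, and Ccl2 at -6.85 and -3.53.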

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

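Scaling to recovered read totals without Purb and Smoc2 was added after the data were seen, and the other 8 settings were planned. With 1 library per group no library could be left out. No paired analysis was possible because each group holds 1 library. Single genes were followed only in the arm in which they are named, a limit set after the values were seen, so a gene that would reverse in the other arm is not counted. Of their values, 1027 stayed within counting error, 500 moved and 23 reversed, a word kept for folds of at least 2-fold whose sign changed. Smaller folds whose sign changed count as moved or, within counting error, as unmoved, and are listed last. A gene with 0 reads in a library has an open interval, so that Csf2 counts as unmoved although its fold with overexpression was -0.52 against the other control. Of the list medians, 648 kept their standing, 33 newly stood apart on either side, 6 no longer did and 6 reversed. Scaling changed the log2 fold of each gene with overexpression, and the median of these changes was 0.11 (median scaling), 0.21 (equal sum), 0.12 (recovered totals) and 0.21 (totals without Purb and Smoc2). The same shifts were 0.06, 0.11, 0.18 and 0.18 for the library labelled Purβ knockdown, and 0.14, 0.24, 0.40 and 0.38 between controls. No list that stood apart changed direction with any of these scalings. The stricter filter and the protein-coding setting test fewer genes, which lowers counts. These settings and the lack of a filter change no gene's fold, so list medians and standings differ there only through the genes tested. For all other differences the cause was not tested.

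With a pseudocount of 0.1, the Purb log2 fold with overexpression was 9.34. Counts with overexpression were 1082 higher and 1175 lower, and 1140 genes were higher in the library labelled Purβ knockdown. CREB-responsive genes with overexpression (0.24) no longer stood apart, and the urea cycle list in the library labelled Purβ knockdown did (-0.69). Without a filter, ribosomal proteins stood apart with overexpression (-0.68). Between controls, fatty acid oxidation (-0.51) and mitochondrially encoded genes (-0.81) then stood apart and CREB-responsive genes (-0.43) did not. With a filter at 5 FPKM, 357 genes were higher and 444 lower with overexpression, 344 higher and 981 lower in the library labelled Purβ knockdown, and 1446 differed between controls. The cell cycle median in the library labelled Purβ knockdown reversed to 0.53, the circadian clock stood apart there (0.79), and interferon genes did between controls (-0.61). With protein-coding genes only, 448 genes were lower with overexpression and 432 higher in the library labelled Purβ knockdown. CREB-responsive genes with overexpression (0.24) did not stand apart and smooth muscle genes did (-0.65).

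Median scaling gave Purb 9.38 with overexpression, and smooth muscle genes stood apart (-0.60). An equal sum gave Purb 9.49 with overexpression and 0.47 in the library labelled Purβ knockdown, 1056 genes higher and 453 lower with overexpression, and smooth muscle genes apart (-0.53). Recovered totals gave Purb 9.45 and 0.58, 1091 genes higher with overexpression and 1162 in the library labelled Purβ knockdown. Because gene length drops out while the pseudocount stays, these counts reflect a changed weight of the pseudocount as well as the scaling. Lists newly apart were smooth muscle (-0.67) and ribosomal proteins (-0.57) with overexpression, the urea cycle in the library labelled Purβ knockdown (-0.48) and endothelial markers between controls (1.61). Totals without Purb and Smoc2 gave Purb 9.55 and 0.58, 1329 genes higher and 462 lower with overexpression, and 1163 higher in the library labelled Purβ knockdown. Smooth muscle (-0.58), the urea cycle (-0.48) and endothelial markers (1.59) stood apart in the same comparisons.

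The other control library as the reference changed most. It crosses vector, infection time and any other difference between the arms, so each fold then contains the difference between the controls. Kupffer cell and macrophage markers, for example, had a median of 2.26 in scramble against β-gal, and the cause of that difference was not tested. Purb was 9.84 with overexpression and -0.22 in the library labelled Purβ knockdown. With overexpression, 1842 genes were higher and 1680 lower. The correlation of the arms reversed to -0.47. Lists newly apart with overexpression were gluconeogenesis (1.76), glycolysis (0.78), glycogen metabolism (1.37), bile acids (0.95), xenobiotic metabolism (3.14), the urea cycle (2.92), hepatocyte secreted proteins (1.28), NRF2 targets (1.13), the circadian clock (1.00), smooth muscle (-2.61), ribosomal proteins (-0.93) and Kupffer cell markers (-1.88). Interferon (-0.45), unfolded protein (0.0038) and immediate early genes (0.59) no longer stood apart. Acute phase (-0.0302), p53 (-0.33) and cell cycle genes (-0.20) moved to the other side of the random lists. In the library labelled Purβ knockdown, glycolysis (-1.64), glycogen metabolism (-2.55), the urea cycle (-3.39), NRF2 targets (-2.35) and Kupffer cell markers (2.24) newly stood apart, and the cell cycle (0.51) and smooth muscle (0.74) reversed. Genes past 2-fold that reversed with overexpression were Cilp2 (0.16), Il23a (2.28), Sprr1b (0.80), Id1 (-2.28), Ccl5 (0.69), Pmaip1 (-0.61), Phlda3 (-0.39), Eda2r (-0.28), Mup14 (1.99) and Areg (0.48). Those in the library labelled Purβ knockdown were Il23a (-4.31), Sprr1b (-2.87), Ccl5 (-2.11), Mup14 (-1.88), Pdk4 (-0.91), Perp (0.48), Cdc20 (0.27), Mki67 (0.28), Plk1 (0.26), Top2a (0.51), Tpm2 (0.0357), Cnn2 (1.29) and Areg (-0.66).

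Folds below 2-fold changed sign mostly with the other control library as the reference. With overexpression these were Pura (-0.35), Purg (-0.07), Pck1 (4.54), Fbp1 (1.81), Pcx (1.72), Adcy6 (-0.94), Crtc2 (0.40), Scd1 (2.12), Me1 (1.05) and Dgat1 (0.07). In the library labelled Purβ knockdown they were Pura (0.36), Adcy6 (0.99), Creb1 (-0.05), Crtc2 (-0.46) and Tpm1 (0.74), beside Purb. With scaling, Pck1 with overexpression (up to 0.22), and Pura (up to 0.15) and Ppargc1a (up to 0.07) in the library labelled Purβ knockdown, changed sign from folds near 0.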

Other observations

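All tests in this part were chosen after the results they bear on were seen, except the match on gene length. The genes in the next 2 paragraphs were picked after their values were seen unless stated.

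Of the 9 measured Kupffer cell and macrophage markers, 7 were 2-fold higher in scramble than in β-gal and Cd14 was 2-fold lower. In the library labelled Purβ knockdown against scramble, 7 were within 2-fold, Cd68 was 2-fold higher and Cd14 2-fold lower. Lyz2, the macrophage lysozyme, stood at 0.117 FPKM in β-gal, 0.515 in overexpression, 34.4 in scramble and 26.5 in the library labelled Purβ knockdown, and the scavenger receptor Marco at 0.120, 0.0704, 14.1 and 12.4. Cd14 stood at 497, 128, 208 and 37.3 in the same order. Other genes were highest in scramble alone. Vim was at 106 FPKM there against 1.38 in β-gal, 1.69 in overexpression and 7.96 in the library labelled Purβ knockdown. Ccn2 was at 44.2 against 0.134, 0.166 and 2.44, Ankrd1 at 22.1 against 0.240, 0.0470 and 1.09, Sox4 at 31.5 against 0.609, 0.438 and 1.55, and Cldn4 at 68.7 against 3.98, 1.16 and 2.08. Tpm2 had 20.1 FPKM in scramble and less than 1 in each of the others. Of cell cycle genes, Mki67 had 9.65 FPKM in scramble and 0.367, 0.411 and 0.664 elsewhere, and Cdc20, Plk1 and Top2a were also highest in scramble, while Ccne2 had 13.2 FPKM in β-gal, 57.6 in overexpression, 16.6 in scramble and 27.1 in the library labelled Purβ knockdown.

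Some RNAs outside protein-coding genes had their highest level in the library labelled Purβ knockdown. The small nuclear RNA Rn7sk had 37.9 FPKM in β-gal, 30.9 in overexpression, 57.8 in scramble and 623 in that library, a ratio to scramble of 10.8 (9.83 to 11.9). In the same order, lincRNA took 0.424%, 0.482%, 0.482% and 0.955% of reads, and small noncoding RNA 0.0137%, 0.0121%, 0.0141% and 0.0454%. Mitochondrial ribosomal RNA took 0.653%, 0.429%, 0.117% and 0.784%, so that scramble was the library apart from the others. In both arms at once, 10 of 20 acute phase genes were 2-fold lower, where independent lists would share 10.4, as were 7 of 17 NF-kB targets, where they would share 5.76. Of p53 targets, Cdkn1a and Pmaip1 were 2-fold higher in both, where they would share 1.75. Lists that did not stand apart in either arm were glucagon and cAMP signalling components (medians 0.15 and -0.14), glycolysis (-0.55 and -0.10), glycogen metabolism (-0.04 and -0.24), insulin signalling (0.02 and 0.03), the urea cycle and amino acid catabolism (0.01 and -0.38), NRF2 targets (-0.20 and -0.29), the circadian clock (0.16 and 0.21), mitochondrially encoded genes (-0.54 and 0.24), Kupffer cell and macrophage markers (-0.07 and -0.17) and liver endothelial markers (-0.11 and 0.01).

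The first pattern is that Purb was not lower in the library labelled Purβ knockdown than in scramble. The 4 other scalings tried do not account for it, since the lowest log2 fold over them was 0.42, against a counting half-width of 0.08. All of them shift the folds of this comparison upward, by a median over genes of 0.06 to 0.18, so a scaling that lowers them was not tried. An exchange of the labels of these libraries remains open: Purb in scramble was 0.765 times that in the library labelled Purβ knockdown (0.723 to 0.810), which such an exchange would need. The fold also lay at the 78.6 percentile of 1209 genes of similar abundance, so that it was no larger than usual between these libraries, and the exchange cannot be told apart from ordinary differences between them. A loss of Purβ protein without a lower transcript, or one that had passed by 30 h, was not tested.

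The second pattern is Smoc2, with 3218 FPKM in β-gal and 0 reads in the other libraries. Fibroblasts or stellate cells in that library do not account for it, as Vim, the most abundant of their 14 listed markers there, reached 0.0428% of the Smoc2 level. Reads shared with the paralog do not either, since Smoc1 reached 1.39% of it. An introduced Smoc2 sequence, such as another virus or a carry-over, remains open: Smoc2 reached 29.5% of the level of the introduced Purb, and the 16 protein-coding genes with reads within 1 Mb had a median log2 fold of -0.10 and a highest of 0.55, but gene-level values cannot separate it from induction of the endogenous gene. Other explanations were not tested.

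The third pattern is the lower level of hepatocyte and acute phase transcripts in the library labelled Purβ knockdown. A lower share of hepatocytes would raise the markers of the other liver cell types, but their 22 measured markers had a median log2 fold of -0.11 (bootstrap interval -0.98 to 0.00). Of these markers, 1 was at least 2-fold higher and 6 were 2-fold lower. The interval resamples genes of 1 pair of libraries, pooled over cell classes. Some of these genes fell strongly, such as Vim from 106 to 7.96 FPKM. The markers did not rise together, but this cannot settle the share of hepatocytes. The hepatocyte list stayed at the 0 percentile among random lists matched on deposited gene length and abundance, whose lowest median was -1.38. Gene length as deposited thus does not account for it. That length belongs to the gene and not to the transcripts present, so a loss by transcript length is not excluded. The acute phase list was not matched in this way. Dilution by reads outside protein-coding genes came to a log2 change of only -0.0247. A response to the virus, a difference between cultures and an effect of Purβ all stay open and untested, and the Purb level gives no support to the last.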
